A study of Sus scrofa with 9 samples.

How the data were processed

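RNA was measured in 9 libraries of primary porcine granulosa cells, 3 each of control, sulforaphane and FSH. Messenger RNA was enriched with oligo(dT) beads and read on an Illumina HiSeq instrument, per the labels' protocols, which name no strand-specific step. The submitters' processing notes name fastp, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, DESeq2, edgeR and the build Sscrofa11.1, without giving role or order. The deposited table gives FPKM (fragments per kilobase of transcript and per unit of library depth), per the file headers. It also gives an estimated count per gene and library, deposited as read counts per the file headers, which the authors made by assigning reads to genes, with a tool not given in the sources used here. Of 1081 rows, 1053 carried an NCBI gene identifier, all of which were found in a reference gene table of the same build, and 28 were assembled loci without such an identifier. In 143 rows a count was not whole, so reads had been divided between loci there, and genes named from these rows are marked in the text. The file symbol equalled the reference symbol for 1052 identifiers. No column of another series was present (0 columns).

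Before the data were examined, the groups, the tests, the gene lists, the cell type markers, the rule for named genes and the alternative settings were fixed. The plan assumed FPKM and a limma test, and provided that edgeR's quasi-likelihood test would become the main test if counts were found, which was the case. Estimated counts were rounded to whole numbers. The table is part of each library, so its column sums are not the depth. Depth was instead recovered from the ratio of count to FPKM, which is the transcript length multiplied by the depth. Relative depth came from 354 genes with at least 100 counts and 5 FPKM in every library. Absolute depth came from 10 genes whose ratio to the annotated gene span reached a common maximum within 0.1%, among 346 genes compared. The recovered depths, with a mean of 18.8 in units of 1e6 fragments and a range of 16.6 to 22.3, entered the test as library sizes without a further factor. How the rows of the table were chosen is not given in the sources used here. The lack of small differences from control in both comparisons means that adjusted p-values refer to this table and not to the whole transcriptome, and that call counts and overlaps against control are not independent of how the rows were chosen.

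Genes with at least 1 FPKM in at least 3 of 9 libraries were tested (919 genes; 162 were left out). All 9 libraries entered 1 fit with 3 group means in edgeR 4.0.16 (R 4.3.3), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors were the log2 fold change divided by the square root of the F statistic. The common dispersion was 0.0118, a biological coefficient of variation of 10.9%. FPKM are given as mean ± SD of 3 libraries. With 3 libraries against 3 the smallest exact two-sided permutation p is 0.1, so no exact test of a single gene could pass.

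Named genes are, per comparison, the 6 largest rises and the 6 largest falls among genes that passed, have a symbol and a mean of at least 1 FPKM, and whose groups do not overlap; the 2 members with the smallest adjusted p in each gene list; and NQO1, HMOX1 and CYP11A1 in every case. For sulforaphane against FSH the lists add no names. Not every gene that this rule selects, and not every member of the gene lists, is named in the text. GCLM, TXNRD1, STAR, CYP19A1, FSHR, CCND2 and MKI67 were also to be named always and are not analysed here. Other genes that the text names are further members of the fixed lists or examples chosen after their values were seen.

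The 18 gene lists were NRF2 target genes, other antioxidant enzymes, steroidogenesis, cholesterol synthesis and uptake, FSH and cAMP response genes, cell cycle, apoptosis, p53 target genes, heat shock response, unfolded protein and integrated stress response, glycolysis and hypoxia response, extracellular matrix, TGF-beta and BMP signalling, NF-kB and inflammatory genes, interferon response, oxidative phosphorylation (0 genes tested), fatty acid synthesis, storage and oxidation, and autophagy. The 10 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2(FPKM + 1) with a mean-variance trend and a preset inter-gene correlation of 0.01. No list's call held with an estimated correlation. Marker lists of granulosa, theca, luteal, stromal fibroblast, smooth muscle, endothelial and surface epithelium cells were averaged per library. Markers of leukocytes, oocytes and erythroid cells had 0 members analysed here.

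The settings fixed in advance were other pseudocounts (0.1 and 5) and limma settings on log2(FPKM), no filter, a mean FPKM of at least 5, median-ratio and quantile scaling, fits of only the groups compared, a replicate block, each library left out in turn, and a 2-fold minimum. The limma fit on log2(FPKM + 1), DESeq2 1.42.0, TMM factors and a division of the controls between the treatments were added after seeing the data, as were a count of genes by direction and a one-sided Fisher's exact test of KEGG pathways. Counts from samples of 1 group differed by more than sampling noise in every pair (chi-square per degree of freedom of at least 2.60), so no library was counted as a duplicate. This covers counting noise only and does not tell separate cultures from repeated libraries of 1 culture. The tests were checked on simulated counts for the 919 genes of sulforaphane against control, with 200 genes changed: 56 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered by edgeR, with 4 of 719 unchanged genes called. Pathway tests and figures used Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.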

Results

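Gene expression was measured by RNA sequencing in granulosa cells of the pig ovary, the somatic cells that surround the oocyte and make oestradiol. The primary cells had been treated with sulforaphane (an isothiocyanate from cruciferous vegetables that activates the transcription factor NRF2), treated with follicle-stimulating hormone (FSH, the pituitary hormone that acts on granulosa cells through cyclic AMP), or left as controls, with 3 libraries per group. The labels give no dose or duration and do not say whether the libraries of a group came from separate cultures or animals, so every p-value below measures only the spread between these samples. The deposited table held 1081 rows, of which 919 passed the filter on low values. It took in between 6.72% and 8.38% of each library's estimated depth (1217490 to 1756337 counts per library). Genes with little difference from control were missing from it: among tested genes the 1st percentile of the absolute log2 fold change was 0.39 for sulforaphane against control and 0.37 for FSH against control, compared with 0.0057 for sulforaphane against FSH. Counts of called genes against control therefore describe the rows of this table and not the share of the transcriptome that changed. The same holds for gene lists, of which between 0 and 11 members were tested out of 23 to 52 listed, and whose other members are not analysed here.

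The first comparison asked which transcripts differed after sulforaphane. All 9 tested of 40 listed NRF2 target genes rose. NQO1, a quinone reductase, was measured at 99.4 ± 22.9 FPKM with sulforaphane and 3.73 ± 0.457 FPKM in controls (SD, n = 3 each), a 26.6-fold rise (chromosome 6, 17292962 to 17302593 in the Sscrofa11.1 annotation). GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, rose 11.3-fold from 35.6 ± 0.963 to 402 ± 48.8 FPKM. SRXN1, which reduces oxidised peroxiredoxins, rose from 23.8 ± 0.664 to 264 ± 3.89 FPKM, and SLC7A11, the cystine importer, rose 13.2-fold from 0.447 ± 0.0404 to 5.95 ± 1.84 FPKM. HMOX1, the haem-degrading enzyme, rose 7.70-fold from 100.2 ± 8.96 to 772 ± 279 FPKM, and is placed on no chromosome in that annotation.

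The remaining members of the list were PIR, GSTA1, EPHX1 and BLVRB, with log2 fold changes of 2.53, 2.97, 1.70 and 1.63. The highest adjusted p in the list was 2.32e-06 for EPHX1 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 9 also passed when adjusted over the list alone. Of all 919 tested genes 915 passed in this comparison, and 900 in FSH against control. That all members of a list passed against control therefore adds no support, here or for the lists below. The list rose relative to the other genes of the table (limma camera with a preset correlation, Benjamini-Hochberg adjusted p = 9.41e-08, 9 genes), which was lost at adjusted p = 0.143 with an estimated correlation. Sulforaphane replicate 3 stood apart from the other libraries of its group here: HMOX1 was at 456 FPKM in it and at 872 and 987 FPKM in replicates 1 and 2, while NQO1 was at 126 FPKM in it and at 87.8 and 84.7 FPKM in the others. Beyond the list, the largest rises included ZFAND2A, a zinc-finger protein induced by arsenite, which rose 15.4-fold to 128 ± 23.0 FPKM, and LOC100526118, annotated as similar to glutathione S-transferase A1, which rose 14.9-fold to 19.3 ± 2.99 FPKM. Reads of LOC100526118, GSTA1 and EPHX1 were partly divided between loci in the deposited counts, so their levels are uncertain.

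**Figure D1:**
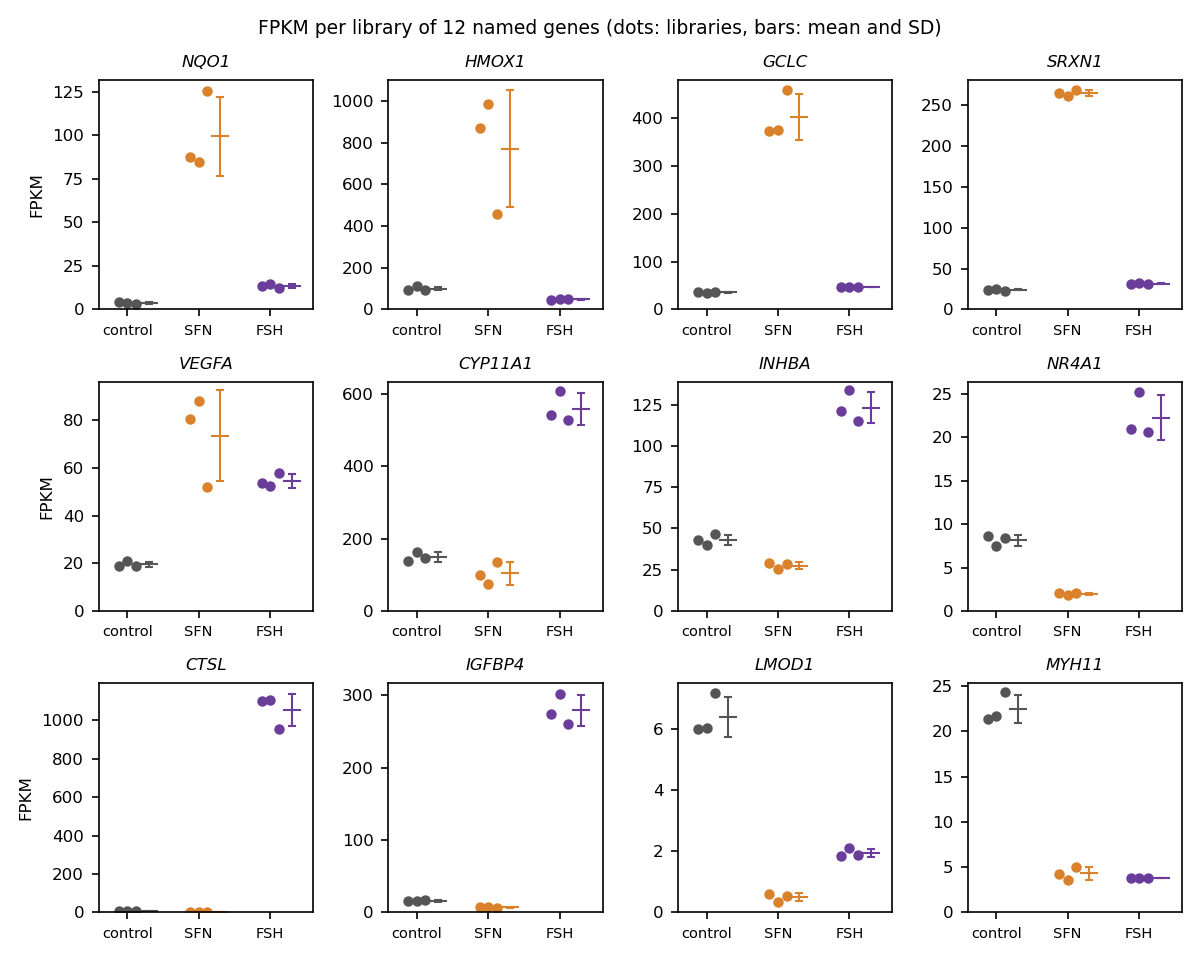
FPKM in each library (vertical axes, linear from 0) of 12 named genes in the control, sulforaphane (SFN) and FSH groups; dots are the 3 libraries of a group, and the bar beside them is their mean with the SD. NQO1, HMOX1, GCLC and SRXN1 lay highest with sulforaphane, whereas CYP11A1, INHBA, NR4A1, CTSL and IGFBP4 lay highest with FSH.

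The 11 tested of 34 listed genes of glycolysis and the hypoxia response all rose with sulforaphane. VEGFA, the angiogenic growth factor, went from 19.6 ± 1.09 to 73.6 ± 19.0 FPKM (3.79-fold), and SLC2A3, a glucose transporter, from 28.6 ± 1.56 to 76.9 ± 5.89 FPKM (2.68-fold). ENO1, a glycolytic enzyme and, among the deposited rows, the gene with most counts in the treated libraries, rose from 1982 ± 116 to 3003 ± 243 FPKM. All 11 passed when adjusted over the list alone, and the list shifted upwards against the other genes (camera, adjusted p = 3.95e-06, 11 genes), a call lost at adjusted p = 0.143 with an estimated correlation. In the list of the unfolded protein and integrated stress response, 5 of 6 tested genes (40 listed) rose, among them DDIT4, an inhibitor of mTORC1 signalling (2.46-fold, 40.4 ± 2.86 to 99.5 ± 4.52 FPKM), and PSAT1, of serine synthesis (2.81-fold, 20.4 ± 3.39 to 57.3 ± 10.3 FPKM), while ATF3, a stress-induced transcription factor, fell by 1.24 on the log2 scale. This list gave an adjusted p = 0.0306 by camera for 6 genes and an adjusted p = 0.143 with an estimated correlation, and it missed the threshold with quantile normalization.

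The 9 tested of 27 listed genes of cholesterol synthesis and uptake all fell with sulforaphane. SQLE, the squalene monooxygenase, went from 7.29 ± 0.994 to 2.84 ± 0.467 FPKM, a log2 fold change of -1.37 ± 0.151 (SE), and INSIG1, the sterol-regulated anchor of SREBP, from 13.9 ± 0.637 to 5.62 ± 0.521 FPKM (2.47-fold lower). With TMM scaling all 9 still lay below 0 and 5 passed. The list shifted downwards (camera, adjusted p = 0.0306, 9 genes), with adjusted p = 0.143 with an estimated correlation. The 4 tested of 28 listed steroidogenesis genes fell as well: CYP11A1, the side-chain cleavage enzyme that makes pregnenolone, from 149 ± 13.4 to 103 ± 31.3 FPKM, FDXR, its electron-supplying reductase, from 12.4 ± 0.762 to 8.58 ± 0.666 FPKM, HSD17B7 from 8.53 ± 0.569 to 4.30 ± 0.350 FPKM and HSD17B1, which makes oestradiol, from 2.90 ± 0.203 to 1.42 ± 0.665 FPKM. The highest adjusted p in both lists together was 0.00926 for CYP11A1 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all members passed when adjusted over the list alone. With median-ratio scaling 3 of the 4 steroidogenesis genes passed, and with TMM scaling 1 of them. The call for CYP11A1 ended with median-ratio scaling (log2 fold change -0.27 in place of -0.53) and with TMM scaling (-0.07).

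The 7 tested of 46 listed extracellular matrix genes fell, with COL1A1, the main fibrillar collagen chain, at 71.4 ± 3.61 FPKM in controls and 31.7 ± 2.70 FPKM with sulforaphane, and COL12A1 at 100.1 ± 6.04 and 41.9 ± 6.17 FPKM. All 7 passed when adjusted over the list alone, and camera gave adjusted p = 0.0306 for the list of 7 genes, against adjusted p = 0.452 with an estimated correlation. With TMM scaling 3 of the 7 passed. Smooth muscle markers were lower in the same libraries: the mean log2(FPKM + 1) of the 5 analysed markers was 5.82 ± 0.0695 in controls and 4.05 ± 0.0526 with sulforaphane (SD, n = 3). Among them LMOD1, an actin-nucleating protein of smooth muscle, fell 12.9-fold from 6.39 ± 0.658 to 0.497 ± 0.129 FPKM. ACTA2, smooth muscle actin and, among the deposited rows, the gene with most counts in the control libraries, fell 3.07-fold from 7303 ± 147 to 2381 ± 108 FPKM (reads partly divided between loci). Keratins listed as surface epithelium markers (KRT7, KRT8 and KRT18) were at a mean log2(FPKM + 1) of 3.83 ± 0.110 in controls and 2.51 ± 0.0971 with sulforaphane. KRT18 did not pass the filter on low values and was not tested by itself. Whether granulosa cells made these keratins was not tested, so the mean does not measure a share of surface epithelium cells. The stromal fibroblast markers THY1, COL1A1 and PDGFRB stood at 4.17 ± 0.0588 and 3.70 ± 0.122, although PDGFRB itself rose 1.38-fold.

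Other large falls were those of GDF6, a bone morphogenetic protein family member (9.96-fold), RRAD, a small GTPase that inhibits calcium channels (8.89-fold, from 195 ± 9.03 to 21.9 ± 4.65 FPKM), CDKN1C, a cyclin-dependent kinase inhibitor (7.97-fold), and HSPB7, a small heat shock protein (7.60-fold). The 6 tested of 52 listed cell cycle genes were lower, with CDC25B, a mitotic phosphatase, at a log2 fold change of -0.76 ± 0.114 (SE) and CCND1, cyclin D1, at -0.58 ± 0.134 (SE). Only 1 of these 6 passed with median-ratio scaling, and E2F1 changed sign with TMM scaling. The list gave adjusted p = 0.320 by camera.

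In the list of FSH and cAMP response genes (10 tested of 46 listed), 5 rose and 5 fell with sulforaphane, including NR4A1, an immediate-early nuclear receptor, which fell 4.15-fold, and VEGFA, which rose 3.79-fold, and camera gave adjusted p = 0.365. Of the p53 target genes 6 fell and 1 rose (camera adjusted p = 0.320), and 4 were lower with median-ratio and 3 with TMM scaling. GADD45B and GADD45A, growth arrest genes, fell from 15.1 ± 1.22 to 5.33 ± 0.587 and from 220.4 ± 5.43 to 110.3 ± 32.5 FPKM, and PHLDA3 changed sign with TMM scaling. Of the genes of TGF-beta and BMP signalling 3 rose and 5 fell (camera adjusted p = 0.797), with the anti-Müllerian hormone receptor AMHR2, whose reads were partly divided between loci, at a log2 fold change of -2.24 ± 0.197 (SE), TGFB3 at -1.07 ± 0.109 (SE), and SMAD6 with a change of sign under TMM scaling. Of 5 inflammatory genes 4 fell, led by the adhesion molecule VCAM1 (-1.94 ± 0.137, SE) and the cytokine IL1A (-0.81 ± 0.153, SE), and CCL2 rose (camera adjusted p = 0.701), and with TMM scaling 1 of the falls passed. In the lists with too few genes for camera, the interferon-induced BST2, PSMB8 and DDX60 fell (1 of the 3 with TMM scaling), CPT1B, of fatty acid uptake by mitochondria, fell by 2.37 on the log2 scale while ACSL4 and PPARG rose, and of the other antioxidant enzymes SELENOP fell 2.73-fold and PRDX6 rose 1.62-fold. In the apoptosis list BBC3, a pro-apoptotic BCL2 family member, fell, the small heat shock protein CRYAB fell by 0.81 on the log2 scale, and the autophagy gene ATG12 rose 1.43-fold (reads of SELENOP, PRDX6 and ATG12 partly divided between loci). With TMM scaling 3 genes were lower in each of the FSH and cAMP list and the list of TGF-beta and BMP signalling, and CRYAB and BBC3 did not pass. With library depths every analysed member of the lists in this paragraph passed both over all genes and when adjusted over the list alone.

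Across the table, 915 of 919 genes passed in sulforaphane against control, 315 of them higher and 600 lower (edgeR quasi-likelihood test, Benjamini-Hochberg at 0.05). The balance depended on the scaling between libraries. The median log2 fold change of all tested genes was -0.56 with the library depths, -0.29 with median-ratio factors and -0.09 with TMM factors. With TMM factors 317 genes were higher and 296 lower. Quantile normalization, used in limma on log2(FPKM + 1), moved the median from -0.45 to -0.21. Falls smaller than these shifts are therefore falls relative to library depth and not relative to the other genes of the table. The other scalings were computed from rows of this table, nearly all of which passed against control. A call lost under them does not show that a gene was unchanged.

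**Figure D2:**
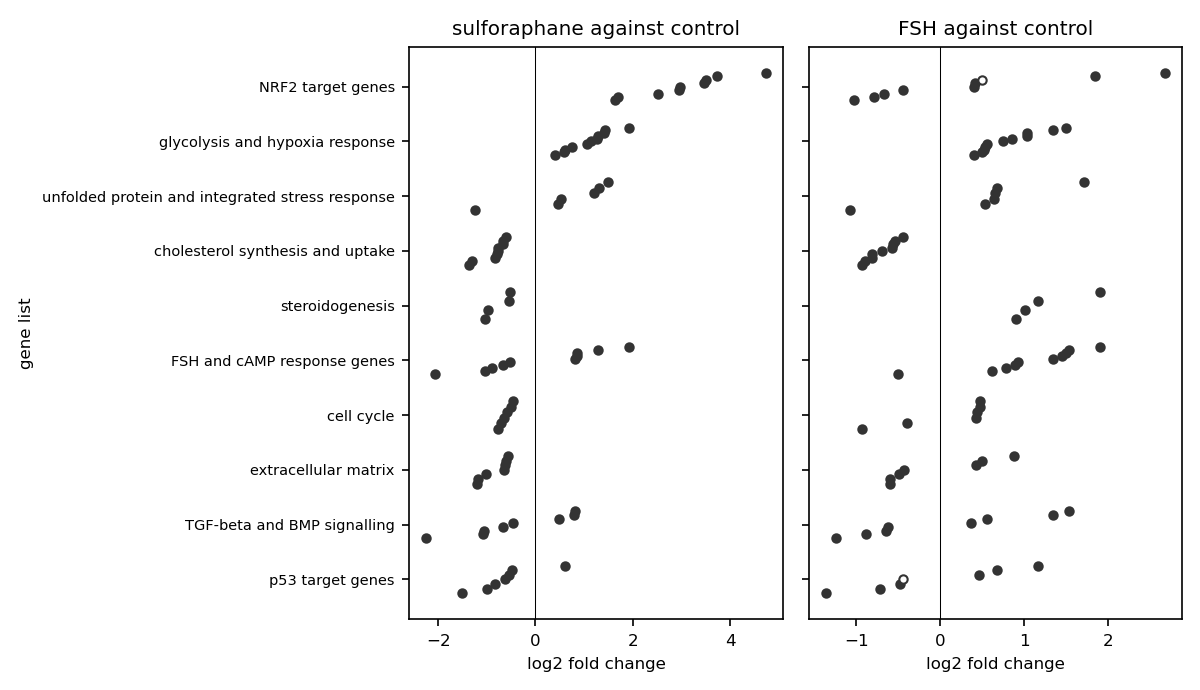
Log2 fold changes (horizontal axes) of the tested members of 10 gene lists (rows), for sulforaphane against control (left) and FSH against control (right); each dot is 1 gene, filled where it passed the test and open where it did not. All 9 tested NRF2 target genes lay above 0 with sulforaphane and were spread on both sides with FSH, while all 9 tested genes of cholesterol synthesis and uptake lay below 0 in both.

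The comparison of FSH with control asked how the cells responded to their physiological hormone. In the list of FSH and cAMP response genes, 9 of 10 rose and ADAMTS1, a protease with reads partly divided between loci, fell. CYP11A1 rose 3.75-fold from 149 ± 13.4 to 558 ± 43.0 FPKM, INHBA, the activin A subunit, 2.88-fold from 43.1 ± 3.18 to 123 ± 9.47 FPKM (reads partly divided between loci), and NR4A1 2.74-fold from 8.14 ± 0.622 to 22.3 ± 2.59 FPKM. The 4 tested of 28 listed steroidogenesis genes rose, with FDXR going from 12.4 ± 0.762 to 28.0 ± 1.26 FPKM. All 10 and all 4 also passed when adjusted over the list alone, and the FSH and cAMP list shifted upwards against the other genes (camera, adjusted p = 0.0186, 10 genes), a call lost at adjusted p = 0.137 with an estimated correlation.

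CTSL, the lysosomal protease cathepsin L, had the largest rise of the tested genes: it stood at 7.28 ± 0.605 FPKM in controls and 1053 ± 83.7 FPKM with FSH, a 145-fold rise (log2 fold change 7.18 ± 0.130, SE, n = 3 per group; adjusted p = 5.96e-13, edgeR quasi-likelihood test, Benjamini-Hochberg). In the Sscrofa11.1 annotation CTSL lies on chromosome 10 from 27668523 to 27674705. IGFBP4, a binding protein of insulin-like growth factors, rose 17.3-fold from 16.1 ± 1.3 to 279 ± 21.2 FPKM. Among genes near the detection limit in controls, SV2C, a synaptic vesicle protein, reached 2.71 ± 0.256 FPKM, SLC46A3, a lysosomal transporter, 4.49 ± 0.212 FPKM and HP, haptoglobin, 15.6 ± 2.34 FPKM, rises of 20.2-fold, 14.2-fold and 13.7-fold.

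The 9 tested of 27 listed genes of cholesterol synthesis and uptake fell with FSH too, including INSIG1 (log2 fold change -0.90 ± 0.0961, SE) and ACAT2 (-0.81 ± 0.0964, SE). Camera gave adjusted p = 0.00564 for the 9 genes and adjusted p = 0.118 with an estimated correlation. The 11 tested of 34 listed genes of glycolysis and the hypoxia response rose, with SLC2A3 at 72.8 ± 3.77 FPKM and VEGFA at 54.5 ± 2.86 FPKM (camera adjusted p = 0.0102, 11 genes, and adjusted p = 0.407 with an estimated correlation). With quantile normalization 8 of the 11 passed and ENO1 changed sign. Both lists passed in full when adjusted over the list alone. DDIT4 rose 3.27-fold and ATF3 fell 2.10-fold in the list of the unfolded protein and integrated stress response, where 5 of 6 genes rose (camera adjusted p = 0.354).

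The NRF2 target genes did not move one way with FSH: 4 rose, 4 fell and SLC7A11 did not pass (0.633 ± 0.0751 against 0.447 ± 0.0404 FPKM), and 8 passed when adjusted over the list alone (camera adjusted p = 0.918). NQO1 rose 3.59-fold to 13.4 ± 1.12 FPKM and GSTA1, whose reads were partly divided between loci, 6.38-fold, whereas HMOX1 fell 2.04-fold to 49.2 ± 2.73 FPKM. Of the other antioxidant enzymes PRDX6 rose 2.32-fold and SELENOP fell 1.59-fold, both with reads partly divided between loci.

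Smooth muscle markers moved both ways with FSH. MYH11, smooth muscle myosin heavy chain, fell 5.87-fold from 22.5 ± 1.58 to 3.82 ± 0.0306 FPKM (reads partly divided between loci) and ACTA2 fell 2.48-fold, while CNN1, calponin of smooth muscle, rose 1.52-fold from 97.3 ± 3.24 to 149 ± 7.36 FPKM. The mean log2(FPKM + 1) of the 5 analysed markers was 5.82 ± 0.0695 in controls and 4.75 ± 0.0764 with FSH, that of the surface epithelium keratins 3.83 ± 0.110 and 3.17 ± 0.0598, and that of the stromal fibroblast markers 4.17 ± 0.0588 and 3.67 ± 0.0896. GDF6 fell 4.84-fold, ANKRD1, a transcriptional cofactor of muscle whose reads were partly divided between loci, 4.62-fold, HDAC9, a histone deacetylase, 4.55-fold, AGTR1, the angiotensin II receptor, 3.95-fold and HSPB3, a small heat shock protein, 3.80-fold. Granulosa markers (6 analysed) stood at 4.08 ± 0.0447 in controls, 3.98 ± 0.0514 with sulforaphane and 4.78 ± 0.0317 with FSH. The theca markers analysed (2 of 9 listed), CYP11A1 and LHCGR, stood at 4.41 ± 0.0985, 3.83 ± 0.265 and 5.66 ± 0.122. The luteal markers (3 of 8 listed), which add PTGFR, stood at 4.43 ± 0.101, 3.80 ± 0.302 and 5.55 ± 0.138. CYP11A1 and LHCGR are also in the list of FSH and cAMP response genes, so these means do not measure the share of theca or luteal cells. The endothelial markers TIE1 and KDR stood at 0.62 ± 0.00195, 0.81 ± 0.128 and 0.94 ± 0.0362, although TIE1 itself fell 2.49-fold with sulforaphane. The higher mean with sulforaphane thus rests on KDR alone, which did not pass the filter on low values and was not tested. Members of the granulosa list also moved both ways: with sulforaphane GJA1, KITLG and FST rose and INHBA, HSD17B1 and AMHR2 fell, and with FSH AMHR2 fell and the other 5 rose.

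Of 6 tested cell cycle genes (52 listed), MCM2, MCM5 and MCM7, subunits of the replicative helicase, and E2F1, a transcription factor of S phase, rose with FSH by log2 fold changes of 0.42 to 0.48 (reads of MCM7 partly divided between loci), while CCND1 and CDC25B fell (camera adjusted p = 0.932). With quantile normalization 1 of these rises and both falls passed. In the extracellular matrix list 3 of 7 rose and 4 fell (camera adjusted p = 0.635), with VCAN, the proteoglycan versican, at 150.1 ± 3.91 against 81.5 ± 5.63 FPKM and SPARC at 708 ± 5.77 against 957 ± 10.9 FPKM. The list of TGF-beta and BMP signalling held 4 rises and 4 falls (camera adjusted p = 0.863), and FST, the activin-binding follistatin, rose 2.54-fold to 50.2 ± 2.01 FPKM. Of the p53 target genes 3 rose, 3 fell, among them PHLDA3, a repressor of AKT (2.57-fold), and BBC3 did not pass (camera adjusted p = 0.767). Of the inflammatory genes 4 fell, with VCAM1 down 2.58-fold and CSF1 1.54-fold, and LIF did not pass (camera adjusted p = 0.0921, and adjusted p = 0.407 with an estimated correlation). PSMB8 fell, and BST2 and DDX60 did not pass, although all 3 did with quantile normalization. ACSL4 rose 1.55-fold while PPARG and CPT1B fell, BBC3 of the apoptosis list did not pass, CRYAB fell 2.22-fold and ATG12 rose 1.33-fold. Adjusted over the list alone, the counts of genes that passed in these lists were the same as over all genes.

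In FSH against control 900 of 919 genes passed, 508 of them higher and the others lower (edgeR quasi-likelihood test, Benjamini-Hochberg at 0.05). The median log2 fold change of all genes was 0.41 with the library depths and 0.58 with TMM factors. In limma on log2(FPKM + 1) it moved from 0.33 to 0.21 with quantile normalization.

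The direct comparison of sulforaphane with FSH asked which responses differed between the treatments. HMOX1 was 15.7-fold higher with sulforaphane (772 ± 279 against 49.2 ± 2.73 FPKM), GCLC 8.54-fold (402 ± 48.8 against 47.1 ± 0.346 FPKM), NQO1 7.41-fold, SLC7A11 9.37-fold, PIR 9.14-fold, ZFAND2A by a log2 difference of 3.47 and IRAK2, a kinase of interleukin-1 signalling, 11.2-fold (15.7 ± 1.29 against 1.39 ± 0.160 FPKM). CTSL was 325-fold lower with sulforaphane than with FSH, and IGFBP4 38.4-fold lower. CYP11A1 was 5.39-fold lower (103 ± 31.3 against 558 ± 43.0 FPKM). OLR1, the receptor of oxidised low-density lipoprotein, was 30.8-fold lower (1.22 ± 0.351 against 37.5 ± 2.54 FPKM), CXCL12, a chemokine, 42.2-fold, ADAMTS4, an aggrecan-cleaving protease, 30.0-fold and RGS4, a regulator of G-protein signalling, 20.2-fold. The highest adjusted p among these genes was 1.15e-07 for CXCL12 (edgeR quasi-likelihood test, Benjamini-Hochberg), which in the sulforaphane libraries was near the detection limit at 0.080 ± 0.0608 FPKM. ADAMTS4 and RGS4 were low there too, at 0.18 to 0.2 and 0.38 to 0.46 FPKM, so the folds of these genes are uncertain.

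Of the 9 NRF2 target genes 8 were higher with sulforaphane than with FSH, and GSTA1 did not pass (26.1 ± 6.63 against 21.3 ± 2.70 FPKM), while all 9 passed with each of the 3 other scalings. The list differed from the other genes of the table (camera adjusted p = 2.11e-10, 9 genes), with adjusted p = 0.103 with an estimated correlation. All 4 tested steroidogenesis genes were lower with sulforaphane, as were 6 of 10 FSH and cAMP response genes (2 higher, 2 not passing) and 5 of 6 cell cycle genes (CCND1 higher). With the other scalings 4 of the cell cycle genes were lower and 1 did not pass. Of the 11 genes of glycolysis and the hypoxia response 4 were higher with sulforaphane and 7 did not pass, against 9 and 2 with each of the 3 other scalings (camera adjusted p = 0.0113, and adjusted p = 0.706 with an estimated correlation). That call ended without sulforaphane replicate 2, at adjusted p = 0.0550 in a range of 0.00146 to 0.706 over all alternatives. Adjusted over the list alone, the same numbers of genes passed in these 5 lists. No other list passed by camera in this comparison. Of the cholesterol genes 4 were lower and 5 did not pass, with a camera statistic upwards and a median below 0, and 6 of the 9 lay below 0 with library depths and above 0 with each of the 3 other scalings.

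In sulforaphane against FSH 512 of 919 genes passed, 119 higher and 393 lower with sulforaphane (edgeR quasi-likelihood test, Benjamini-Hochberg at 0.05), and 407 did not pass. The split was 292 higher and 334 lower with median-ratio factors, 320 and 327 with TMM factors, and 399 and 302 with quantile normalization, so the excess of lower genes holds for scaling to library depth. The median log2 fold change moved from -0.18 to 0.08 with median-ratio factors and to 0.12 with TMM factors. In limma on log2(FPKM + 1) it moved from -0.14 to 0.18 with quantile normalization.

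**Figure D3:**
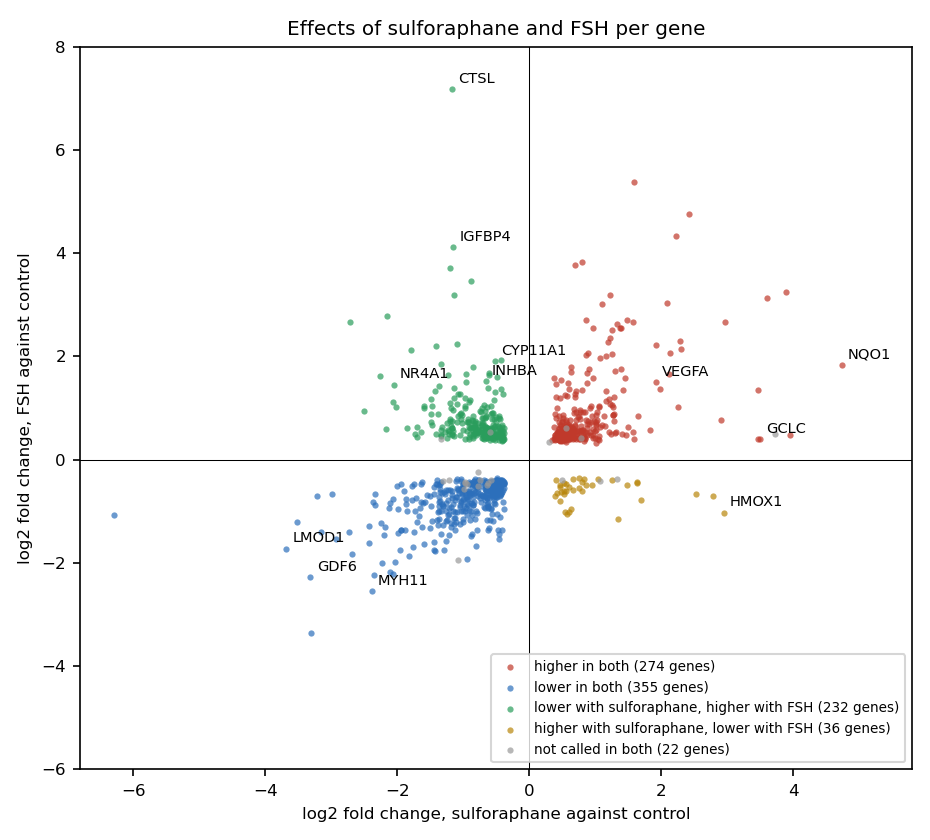
Log2 fold change of each of 919 tested genes for sulforaphane against control (horizontal axis) and FSH against control (vertical axis), coloured by direction among the 897 genes that passed in both comparisons, with 22 others in grey. The lower left (355 genes) and upper right (274 genes) quadrants hold most genes, the upper left holds 232 (93 with TMM factors) and the lower right 36, and the band around 0 on each axis is empty because such genes are not in the table.

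Genes that passed against control in both treatments numbered 897. Of these, 274 were higher in both, among them VEGFA, SLC2A3, DDIT4 and NQO1, and 355 were lower in both, among them GDF6, VCAM1, INSIG1 and ACTA2. A further 232 were lower with sulforaphane and higher with FSH, among them CTSL, IGFBP4, CYP11A1, INHBA and NR4A1 (CYP11A1 left this class with median-ratio and TMM factors, where its fall with sulforaphane did not pass), and 36 were higher with sulforaphane and lower with FSH, among them HMOX1, PIR, BLVRB and PPARG. Scaling changed the size of the class lower with sulforaphane and higher with FSH, which held 168 genes with median-ratio factors, 121 with quantile normalization and 93 with TMM factors, while genes of the same direction numbered 565, 514 and 464. Without any relation between the lists of called genes, 174 would have been higher in both, 256 lower in both, 332 lower with sulforaphane and higher with FSH, and 134 the reverse. These numbers leave out the shared control libraries and the choice of rows, so they are no measure of a shared response. Simulated unchanged groups with shared controls had the same sign in 66.7% of genes. That share follows from the shared controls whatever the size of the noise. It is therefore no baseline for genes whose effects are larger than the noise.

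Across the 919 genes, which are not independent replicates, the log2 fold changes of both treatments correlated at r = 0.472 (Spearman 0.439), and 70.3% had the same sign. Because both effects were measured against the same 3 control libraries, 100 simulations of unchanged groups gave a mean correlation of 0.499 and the same sign in 66.7% of genes. Both values follow from shared controls whatever the size of the noise, so they are no baseline for effects larger than the noise. The covariance, which does depend on the size of the noise, was 0.537, against 0.0132 in the simulations. With 1 control library for one treatment and the other controls for the other, the 6 possible divisions gave correlations of 0.446 to 0.467 and the same sign in 70.2% to 70.3% of genes. Genes with small effects against control are not in the table.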

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

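The counts of other splits of the libraries and the slope for sulforaphane replicate 3 were planned, while the tests of variance share, FSH RNA, shared control noise, divided controls, scaling, handling of the cultures and smooth muscle markers were chosen after the results had been seen.

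Effects of sulforaphane and FSH against the same controls differed in direction for 232 genes lower with sulforaphane and higher with FSH, and for 36 genes higher with sulforaphane and lower with FSH. Each passed the test of the difference (edgeR quasi-likelihood test, Benjamini-Hochberg), which follows nearly by construction from called effects of opposite sign and adds no support. The first set included CTSL, IGFBP4 and NR4A1, and the second HMOX1, PIR, CCL2 and PPARG. With TMM factors, added after seeing the data, the sets held 93 and 27 genes. The difference in treatment stays open as its explanation and was not tested further.

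Splitting the 6 libraries of a comparison differently allows only 10 splits, too few for a share under 0.05. In sulforaphane against control the real split gave 915 genes and the highest other split 0, so 1 split gave as many. In FSH against control these counts were 900 and 0 (1 split), and in sulforaphane against FSH 512 and 0 (1 split), all by edgeR; at an unadjusted p under 0.05 the highest other splits gave 15, 1 and 41 genes. For gene lists by camera the real split gave 5 lists and the highest other 5 in sulforaphane against control (2 splits gave as many), 3 and 4 in FSH against control (6 splits), and 2 and 2 in sulforaphane against FSH (7 splits). The table appears to hold genes chosen for a difference between the real groups, which favours the real split in both comparisons with control. Every other split also has libraries of both groups on both sides. It therefore keeps part of the treatment difference, which lists can still follow, and adds the rest to the spread, which lowers gene calls. Neither the gene counts nor the list counts of other splits thus show what unchanged groups would give.

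Most genes moved the same way under both treatments: 629 of the 897 genes that passed in both. Noise of the shared control libraries gave 2.47% of the observed covariance in simulations. Over 6 divisions of the controls between the treatments the mean correlation was 0.456, against 0.472 with shared controls. The simulations applied no choice of rows, and the divisions reused rows that appear chosen for a difference from these same controls. Neither result alone therefore decides whether this noise is the main source. The residual SD of the control libraries was 0.124 to 0.150 on the log2 scale. Genes higher in both had median log2 fold changes of 0.70 with sulforaphane and 0.60 with FSH, and genes lower in both -0.88 and -0.70. Effects of this size argue against noise between the control libraries as the main source, for these rows. A difference common to all control libraries is not covered by this. A single scaling factor between control and treated libraries would move these genes one way, whereas 43.6% of them moved in the less frequent direction. The labels name no other difference between the control cultures and both treated sets; one that followed these groups would be confounded with treatment, and the 394 of 629 genes that did not pass the test of sulforaphane against FSH do not decide it. A response that both treatments share stays open as an untested explanation.

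Sulforaphane replicate 3 stood apart from the other libraries of its group. Its residual SD was 0.288 on the log2 scale against 0.187 and 0.226 in replicates 1 and 2, and its counts differed from theirs by a chi-square per degree of freedom of 52.8 and 60.7, against 6.5 between those. A uniformly weaker response as the whole difference is argued against, since the effect in another library took up 4.16% of the variance of the difference, and RNA of an FSH-treated culture at a share of 0.5% or more is argued against by CTSL and IGFBP4, which implied shares of 0.0614% and -0.551%. The limit of 100 FPKM that chose these 2 of 7 genes was set after the values were seen; of the others OLR1, CXCL12 and CITED1 implied 1.37%, 0.939% and 1.90%, and an earlier test by the median of all 7 decided nothing. If all CTSL in that library came from such RNA, its share would be 0.349%. A weaker response in that culture as part of the difference stays open at a slope of -0.084 (SE 0.0134), which lay between the bounds set for and against it. The slopes of a group's libraries cancel by construction, and sulforaphane replicate 2 had one of 0.0783 (SE 0.0118), with 4.36% of the variance. The size of the slope is therefore not particular to replicate 3. A different cell preparation, for which no test was run, stays open as well.

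Smooth muscle markers were lower on average under both treatments. Fewer smooth muscle cells would lower all 5 markers by about the same factor. With FSH their log2 fold changes spanned 3.16 (SE 0.155), from -2.55 for MYH11, whose reads were partly divided between loci, to 0.61 for CNN1, which argues against a loss of these cells as the whole cause. With sulforaphane all 5 fell and spanned 2.52, but LMOD1 and DES were below 1 FPKM there, and the 3 others spanned 1.22 (SE 0.156), from -2.39 for MYH11 to -1.17 for CNN1, so fewer smooth muscle cells stay open for sulforaphane, and as a part of the change for FSH. Granulosa cells may also express some of these genes, which was not tested here.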

How the results depend on the processing

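TMM factors, DESeq2, limma with trend on log2(FPKM + 1), divided controls and the counts by direction were chosen after seeing the data; the other settings were planned. No called direction reversed among the 98 named gene results, and 90 of them kept their call under each of 22 alternatives in which they were tested; 24 of the 98 were not tested at a mean FPKM of at least 5. In sulforaphane against control, CYP11A1 lost its call with median-ratio factors, CCND1 and BBC3 with median-ratio factors and quantile normalization, and these and FDXR, CRYAB, IL1A and PSMB8 with TMM factors. In FSH against control E2F1 lost its call with quantile normalization. The scalings moved the median gene, which shows how these calls ended. Median-ratio and TMM factors take the typical gene as unchanged, and quantile normalization takes all libraries as alike in distribution. All were computed from rows of this table, where 915 and 900 of 919 genes passed against control with library depths. That premise cannot be relied on in such rows, so a call lost under these scalings does not show an unchanged gene. Which scaling is right was not tested.

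A mean FPKM of at least 5 left fewer genes to test and gave 489 genes in sulforaphane against control, 485 in FSH against control and 292 in sulforaphane against FSH, with 342 in the same and 143 in opposite directions and a correlation of 0.432. At least 2-fold changes numbered 315, 214 and 300. Genes in opposite directions fell to 157 with quantile normalization and to 120 with TMM factors. The correlation was 0.437 with log2(FPKM + 5) and 0.526 with no filter; the cause was not tested. Camera with an estimated correlation called 0, 0 and 0 gene lists, with 3, 2 and 1 at an unadjusted p under 0.05, while fry, which compares a list with no other genes, called 9, 6 and 8. DESeq2 gave 915, 896 and 507 genes, and edgeR with no filter 1078, 1061 and 570.

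Without 1 library at a time, the counts were 892 to 915, 857 to 919 and 470 to 593 genes, 595 to 634 in the same and 245 to 273 in opposite directions, and 5 to 5, 3 to 3 and 1 to 2 gene lists, with 1 list in sulforaphane against FSH without sulforaphane replicate 2. Without sulforaphane replicate 3 the counts were 907, 919 and 593. A replicate block gave 915, 903 and 505 genes. Libraries of the same number correlated above 0.1 in 2 of 9 pairs, in a range of -0.180 to 0.197. Of the 9 libraries, 6 correlated best with a library of their own number. Whether the numbers pair the libraries therefore stays open.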

Other observations

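The pathway test and the genes of this part were chosen after the values had been seen.

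A test of 89 KEGG pathways in the 4 direction classes (356 one-sided Fisher's exact tests on 383 genes) gave 0 pathways at an adjusted p under 0.05 and 18 at an unadjusted p under 0.05. The lowest p by Fisher's exact test was that of HIF-1 signaling, with 9 of its 13 genes higher in both treatments (p = 0.00264, Benjamini-Hochberg adjusted p = 0.940), including VEGFA, PDK1, TFRC and VHL.

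Assembled loci with the symbols gag and pol, which name retroviral genes, were higher in both treatments. The pol locus MSTRG.15538 was at 46.9 ± 5.54 FPKM in controls, 121 ± 12.8 with sulforaphane and 274 ± 17.0 with FSH, and the gag locus MSTRG.15537 at 38.3 ± 2.88, 96.0 ± 6.42 and 236 ± 6.73 FPKM (SD, n = 3). Their reads were divided between loci, so the copies they came from are not known. KCNA5, a potassium channel gene with a mean under 1 FPKM, was at 1.68 ± 0.163 FPKM in controls, 0.020 ± 0.020 with sulforaphane and 0.793 ± 0.0611 with FSH.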
